A study of Zea mays with 229 samples.

How the data were processed

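The series measured maize (B73) leaf protoplasts, plant cells freed of their walls, by the TARGET assay. In this assay a plasmid carrying a transcription factor is introduced into protoplasts and the genes that respond are read by RNA sequencing. Per the labels' protocols, protoplasts came from dark-grown seedlings, received the p1107 plasmid with a factor or the empty vector, were sorted for red fluorescence, and were made into Lexogen QuantSeq libraries, which read the 3' end of messenger RNA. The labels give 229 libraries in 11 batches, 77 with the empty vector and 152 with 1 of 23 factor plasmids. Of these, 115 were with nitrogen and 114 without. Groups of 1 plasmid, nitrogen condition and batch held 2 to 4 libraries, and whether replicates came from separate protoplast preparations is not given in the labels.

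The authors deposited 1 table of edges, each a regulator identifier, a target identifier and both joined. It holds text identifiers only, with no count, fold change, direction, p-value, nitrogen condition or batch beside an edge. Per the submitters' processing notes, featureCounts, edgeR and the genome build B73 RefGen_v4 were used. Their versions, the thresholds and how nitrogen conditions and batches were combined are not given in the sources used here. The depth per library is therefore unknown, and no interval or error can be put on a single edge. The tests fixed before the data were examined assumed fold changes and p-values; those on direction, nitrogen and stricter thresholds were not run.

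The table had 94256 rows and 92485 distinct edges, and 1771 edges of the regulator G2 stood in it 2 times. Distinct edges were used throughout. Identifiers in the sample titles matched 20 of the 23 regulators to a plasmid and so to a batch and, by the plasmid's name, a family. The other 3 (Zm00001d003176, Zm00001d032024 and Zm00001d033859) are given by identifier and were left out of tests on batch and family. The titles give no identifier for the plasmids KN1, of the batch of MYB21 and GLK44, NLP3, of the batch of MYB56, and ZmMYB38. These plasmids were not assigned to the 3 regulators. The reference gene table belongs to another assembly (Zm-B73-REFERENCE-NAM-5.0), and 5 of the 19787 targets, all microRNA genes, matched it. The rule for named genes asked for symbols, direction and p-values. It left the 5 microRNA genes, the regulators and the genes with the most regulators, of which 4 are printed. The keyword lists of genes fixed beforehand could not be applied without gene descriptions.

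Overlap between 2 lists was tested with Fisher's exact test, one-sided, among the 19787 listed genes, with Benjamini-Hochberg adjustment over 253 pairs. The log2 odds ratio was computed with 0.5 added to each cell. Because Fisher's exact test ignores that some genes are listed often, 1000 random tables were also drawn that keep each list's length and each gene's number of regulators. These tables were added after the data had been examined. Since they keep the total of shared genes, pairs above their expectation are balanced by pairs below it. Same-batch pairs share empty vector libraries if each factor was compared within its batch, which was assumed here and is not given in the sources used. For each, unchanged groups were simulated against the empty vector libraries of 1 shared batch, taking both nitrogen conditions together, and lists of the observed lengths were formed from the largest differences. Family and batch labels were permuted 100000 times over the 20 matched regulators. Genes with many regulators were compared with 1000 random tables that keep list lengths only and draw from the 19787 listed genes.

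The overlap tests were tested on simulated data of 19787 genes. Fisher's exact test called 5 of 5 planted pairs and 1 of 248 others. In simulated tables without any pair-specific sharing, in which genes differed in how often they were listed, it called 253 of 253 pairs. With the number of regulators per gene kept, 0 pairs were called where edges followed additive log odds and 26 where genes were drawn with unequal weights, with an excess of at most 0.07 on the log2 scale. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.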

Results

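The data were the authors' deposited table of edges from 23 regulators to 19787 target genes in maize leaf protoplasts. An edge names a gene that the authors listed as responding to a regulator introduced on a plasmid, compared with the empty vector. The table has no direction or size for an edge, so a target may have risen or fallen, and no error can be given for it. Most of the 152 factor libraries came as 6 per factor, and G2 had 14 libraries from 2 batches.

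How many genes responded to each regulator was asked first. In the authors' deposited table NAC61 had 8286 targets, the longest list, and bZIP9 had 8080. HB6 followed with 6677, MYB121 with 6491, WRKY107 with 6401 and NAC5 with 6045. G2, the Golden2 regulator of chloroplast development, had 5569. The shortest lists were those of NAC109 with 658 genes and Zm00001d033859 with 663. The median over regulators was 4002 targets. For 22 regulators the list held the regulator's own gene, and for NAC109 it did not. The plasmid's own transcript can be counted as the gene, so such an edge checks the label and shows no self-regulation. For a single regulator the check is weak. A plasmid transcript may lack the counted 3' end, and 37.5% of possible edges between different regulators were also listed. Of the NAC61 targets, 954 were listed for no other regulator, against 0 of the NAC109 targets and 2 of those of Zm00001d003176. List lengths also depend on thresholds and depth, which are not given in the sources used here, and were not tested against each other. For Zm00001d003176 the list fell from 1870 to 535 genes without a stretch of rows that also stands in the MYB56 list, an alternative chosen after seeing the data. For G2, 1771 of its 5569 targets were listed 2 times.

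**Figure D1:**
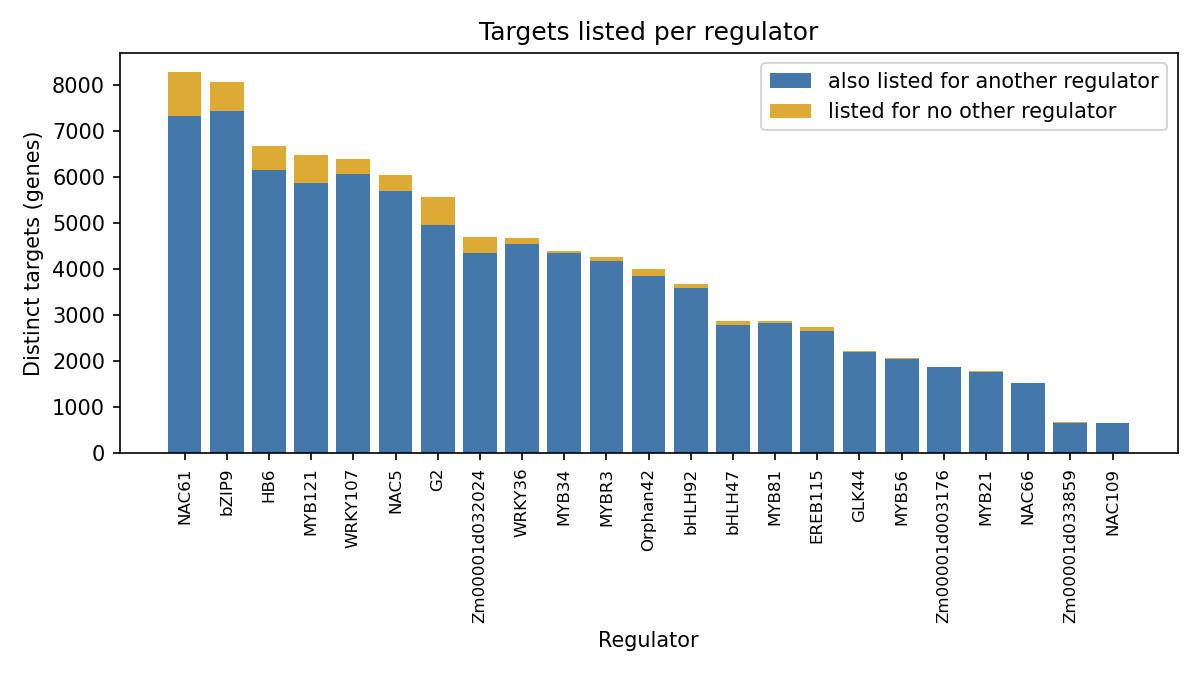
Distinct target genes per regulator (vertical axis, genes; horizontal axis, regulators by list length), with genes listed for no other regulator in yellow. Lists run from 8286 genes for NAC61 to 658 for NAC109, which has 0 genes of its own.

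Whether regulators shared targets was tested for all 253 pairs. The closest pair was Zm00001d003176 and MYB56, with 1527 shared genes and a log2 odds ratio of 7.17. Without the stretch of rows of Zm00001d003176 that also stands in the MYB56 list, they shared 192 genes, with a log2 odds ratio of 2.38. The remaining rows of Zm00001d003176 had 1.41 to 2.81 with the other regulators. Since all rows left out stand in the MYB56 list, a lower value with MYB56 follows by construction. That MYB56 was then no longer the closest list therefore decides nothing. Of these 192 genes, 81 belong to a MYB56 stretch of 1044 rows whose other 963 genes were in the rows left out. NAC109 shared 595 of its 658 targets with MYB34 (log2 odds ratio 5.24) and 588 with MYBR3 (5.13). MYB34 and MYBR3 shared 2957 genes (4.48), against 945 for independent lists. These 3 factors were tested in the same batch. Zm00001d033859 shared 383 of its 663 targets with MYB21 (4.13). Its next closest list was that of GLK44, of the batch of MYB21, with 320 shared genes (3.09). NAC66 (3.05) and MYB81 (2.98), of other batches, were close behind. The batches of Zm00001d003176 and Zm00001d033859 are unknown, and a batch shared with MYB56 or MYB21 is not ruled out, since each of those batches also held a plasmid without an identifier. The lowest log2 odds ratio, 0.59, was that of NAC61 and G2, with 2732 shared genes against 2332 for independent lists. That pair lay below the 3266 ± 28.6 (SD) shared genes of random tables that keep each gene's number of regulators. By Fisher's exact test all 253 pairs passed, the largest adjusted p being 4e-22, and the median log2 odds ratio was 1.75. In simulated tables where genes differed only in how often they were listed, the same test also called 253 pairs, so it does not separate pairs from one another. With the number of regulators of each gene kept, 100 pairs lay above expectation, 92 below and 61 neither. In 1 kind of simulated table without such pairs, 26 pairs were called. The 3 counts include the rows of Zm00001d003176 that also stand in the MYB56 list, and were not redone without them. Zm00001d003176 and MYB56 shared 1527 genes against 490.7 expected. Since the random tables keep the total of shared genes, this excess is balanced by other pairs below expectation.

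The 20 pairs of the same batch had a mean log2 odds ratio of 2.34 ± 1.25 (SD), and the 170 pairs of different batches had 1.67 ± 0.46. The difference of 0.67 had a permutation p of 0.00011 (one-sided, batch labels permuted over 20 regulators). Without the 3 pairs of MYB34, MYBR3 and NAC109 it was 0.21 (permutation p = 0.0161). Simulated unchanged groups against shared empty vectors gave a mean log2 odds ratio of 1.15, from 0.59 to 1.99. All but Orphan42 and G2 among the same-batch pairs lay above their simulated value, 19 in number. The 2 lowest same-batch pairs, G2 with Orphan42 (0.83) and with EREB115 (1.11), use a G2 list that joins 2 batches, only 1 of which they share. The empty vector libraries could not be split here, so part of the excess over either value can come from them.

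**Figure D2:**
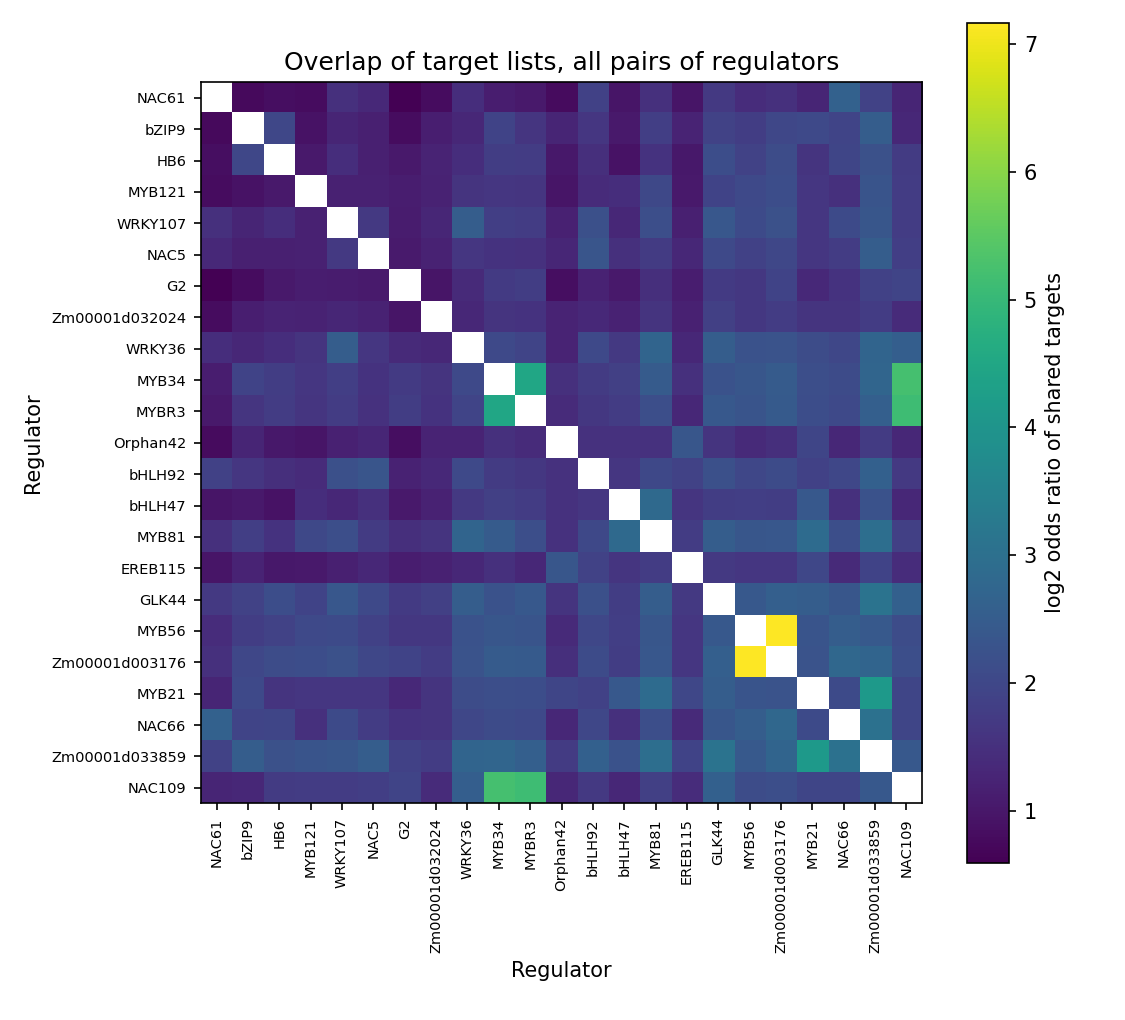
Log2 odds ratio of shared targets (color scale) for each pair of regulators on both axes, ordered by list length. Zm00001d003176 with MYB56 stands out at 7.17 (2.38 without the rows that also stand in the MYB56 list), and MYB34, MYBR3 and NAC109 form a group from 4.48 to 5.24.

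Whether regulators of 1 family shared more targets was asked for MYB, NAC, WRKY, bHLH and GLK factors. Among the 5 MYB factors, MYB21 and MYB81 were closest, with 851 shared genes and a log2 odds ratio of 2.88. In this family 8 of 10 pairs lay above expectation with the number of regulators per gene kept. WRKY36 and WRKY107 shared 2947 genes (2.53), also above expectation. Among the 4 NAC factors, NAC61 and NAC66 shared 1218 genes (2.63) and were the 1 pair of 6 above expectation, while NAC61 and NAC109 (1.28) lay below. GLK44 and G2 shared 1157 genes (1.71), where 1166 ± 20.6 (SD) would follow from the number of regulators per gene. bHLH47 and bHLH92 shared 1041 genes (1.62) and lay below expectation. The 19 same-family pairs averaged 2.03 ± 0.45 (SD) and the 171 others 1.71 ± 0.63, a difference of 0.32. The permutation p was 0.0367 one-sided, the direction asked beforehand, and 0.0535 two-sided. With the Jaccard index the difference was -0.013 (permutation p = 0.711), so the call depended on the measure of overlap.

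Genes that responded to many regulators were counted next. Zm00001d021935 and Zm00001d036946 were listed for all 23 regulators, and Zm00001d007381 and Zm00001d008793 for 22, with NAC109 the exception. At least 12 of the 23 regulators listed 1832 genes, against a mean of 7.58 genes and at most 16 in 1000 random tables of the same list lengths. These tables give every listed gene the same chance. The excess therefore restates that the lists overlap, and its source was not tested. Without the rows of Zm00001d003176 that also stand in the MYB56 list, the count was 1747. At the other end, 5167 genes (26.1%) had exactly 1 regulator, against a mean of 545 in the random tables. Those tables drew only from the 19787 listed genes. Genes that no regulator listed were left out, so the difference at this end depends on that background and decides nothing. At least 8 regulators listed 4229 genes, where random tables gave a mean of 1363.

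**Figure D3:**
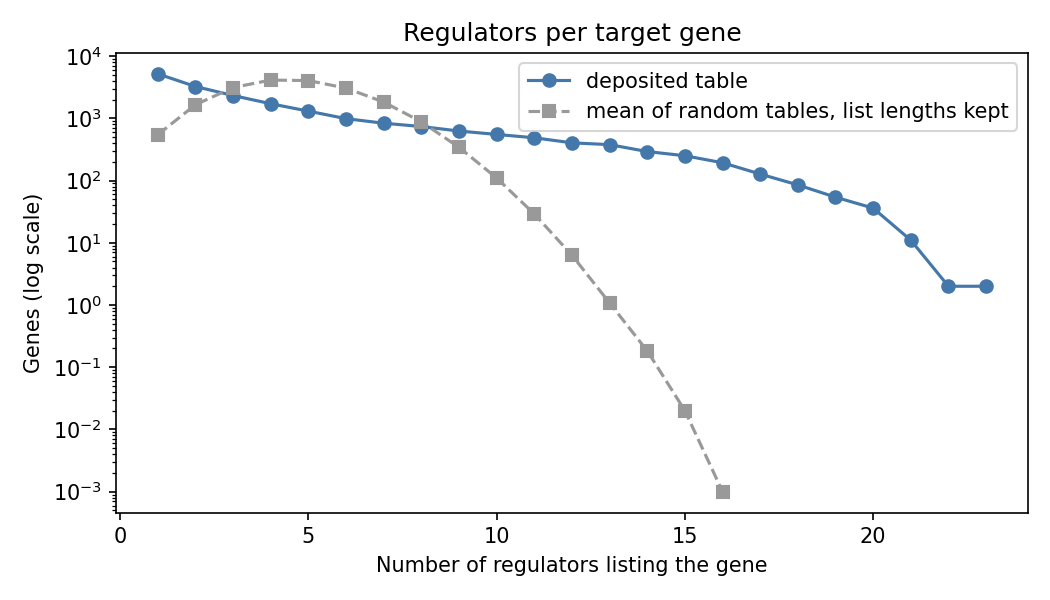
Number of genes (vertical, log scale) by the number of regulators that list them (horizontal), in the deposited table (circles) and as the mean of 1000 random tables of the same list lengths (squares). The deposited table has more genes at both ends, with 5167 genes at 1 regulator and 2 genes at 23. Random tables drew from listed genes only, and the difference at 1 regulator depends on that background.

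Which regulators were targets of one another was described from the edges among them. HB6 was listed for 16 other regulators, NAC5 and Orphan42 for 15 each, and GLK44 for 14. EREB115, MYB81 and Zm00001d032024 were listed for 13 each. bHLH92 was listed for WRKY107 alone, MYB21 for HB6 alone and WRKY36 for NAC61 alone, and Zm00001d033859 for no other regulator. In the outward direction HB6 listed 16 of the others, and G2 and WRKY107 listed 14 each. G2 listed GLK44, and GLK44 did not list G2. In all, 190 of 506 possible edges (37.5%) between different regulators were in the authors' deposited table. Each regulator was listed for 8.26 others on average, above the 4.67 regulators of random sets of 23 listed genes (permutation p = 0.00023, one-sided). The random sets were of any listed genes, not of transcription factors or of genes with like expression. How the authors chose the regulators was not accounted for either. In 47 pairs both regulators listed each other, 12 of them with HB6. Random tables with the same margins gave 45.8 ± 3.53 (SD), with a permutation p of 0.413. Those margins counted the own-gene edges of 22 regulators, which the random tables could move to other regulators. This raises the random value, so the comparison does not decide whether mutual listing was more frequent than the margins give.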

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

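The tests in this part were chosen after the results were seen. They use the order of rows in the authors' deposited table, which the comparisons did not use. The table falls into 42 runs of consecutive rows of 1 regulator. Which experiment or nitrogen condition a run stands for is not given in the sources used here and was not inferred.

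All 1335 genes of the longer run of Zm00001d003176 were also in the MYB56 list, and the run began with MYB56's own gene. Of these, 963 were shared with the MYB56 run that lacks its own gene, and all 963 stood in identical order. The remaining 81 genes of that MYB56 run all stood in the shorter run of Zm00001d003176. Among runs of any other 2 regulators that shared at least 100 genes, the highest rank correlation of row order was 0.69. It was that of MYBR3 and MYB34, of the same batch. This argues against shared empty vector libraries as the source of the identical order, and does not bear on the number of shared genes. The 2 listings of G2, under 1 identifier, correlated in row order at most at 0.63. That is a single comparison, and the G2 libraries differ in batch and title. By itself it decides little. Of 690 pairs of runs from different regulators with at least 100 shared genes, however, only this 1 stood in identical order. For these 963 genes, that argues against separate measurements of 2 factors acting on the same genes as the source of the order. The number of shared genes is not addressed by it. The other 372 genes stood in the second MYB56 run, where row orders correlated at 0.80 and were not identical. A MYB56 list entered under a second regulator may account for the 963 genes, as a hypothesis, and the order of the 372 leaves the rest of the run open.

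G2 had 1771 edges listed 2 times, in 4 runs. The only pairing of these runs without a gene shared inside a pair gave 2 listings of 2487 and 4853 genes, so all repeated genes fall between the listings by that choice. They shared 71.2% of the smaller listing, with a log2 odds ratio of 3.51, against at most 2.27 between the smaller listing and any other regulator. In 200 random tables with list lengths and regulators per gene kept, 1539 ± 29 (SD) and at most 1613 genes were shared when the pairing was chosen again in each table, which argues against often-listed genes as the whole source. Random tables shared 2238 genes on average over all 6 pairs of runs, above the 1771 observed. That decides nothing, since runs of 1 regulator shared 0 genes in the 16 other regulators with 2 runs. The tables with the pairing chosen again lack this rule too. With each listing kept whole, random tables shared 1158 ± 23 (SD) and at most 1215 genes, but that pairing was taken from the data. The row orders of the 2 listings correlated at most at 0.63, which argues against 1 list entered a second time. The labels hold G2 libraries in 2 batches under different titles, so batch and any difference in construct cannot be told apart. Genes that respond to G2 in both batches stay open, as do technical sources not tested here.

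Zm00001d032024 was the regulator with 122 targets under ENSRNA identifiers, and the other 22 regulators had 0. It was also the only regulator with targets under GRMZM5G identifiers, 4 in number. Whether all lists were counted on the same annotation is not given in the sources used here. No preference of this regulator for such genes is therefore read from these counts.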

How the results depend on the processing

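Alternatives named for a run of rows, a listing, the number of regulators per gene, protein coding genes or MYBR3, and the same-batch test with its alternatives, were chosen after seeing the data. All 253 pairs passed Fisher's exact test with genes of at least 2 regulators as background and without the longer run of Zm00001d003176. They also passed with all reference genes or the protein coding ones, which supplied only a larger number of genes and so could only raise each odds ratio. With the number of regulators per gene kept, 100 lay above expectation, a count not redone without the longer run of Zm00001d003176. The family difference of 0.32 was 0.44 in pairs of different batches (permutation p = 0.00052) and reversed to -0.013 with the Jaccard index (permutation p = 0.711); the cause was not tested. Genes of at least 12 regulators numbered 1832, and 1523 to 2221 when the factors of each of 9 batches were left out and the minimum followed the number of factors. With at least 8 regulators, a lower minimum by construction, they numbered 4229. Without its longer run, Zm00001d003176 had 535 targets in place of 1870 and a log2 odds ratio with MYB56 of 2.38 in place of 7.17, lower by construction since shared genes were taken out. G2 had 1771 targets when edges listed 2 times were required and 2487 in the smaller listing alone. The same-batch difference kept its direction and its side of the threshold in its 4 alternatives, as did the family difference in its 3 others. Not run were an adjusted p under 0.01, a log2 fold change of at least 1, shared direction, nitrogen dependence, gene lists and leaving out replicates, since the edges carry none of these values. No paired analysis was possible because the table holds no values per library. Depth limits which edges were listed and is unknown here.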

Other observations

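The tests in this part were chosen after the results were seen. In all, 5 microRNA genes were targets. MIR171h, of a family that acts on GRAS transcription factors, was listed for 8 regulators, NAC5, NAC61, bHLH92, Orphan42, MYB121, WRKY107, GLK44 and G2. MIR171i was listed for MYB121 and G2. MIR169l, of a family that acts on NF-YA factors, was listed for NAC5 alone, MIR396a for NAC61 alone and MIR397a for MYB121 alone.

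Targets with consecutive identifiers were listed for the same regulator 13243 times, against 12441 ± 60.2 (SD) in 1000 random tables with list lengths and regulators per gene kept, a ratio of 1.06. The permutation p was 0.000999, the smallest these tables can give. After Benjamini-Hochberg adjustment 10 of 23 regulators passed, among them MYB21 (121 pairs, ratio 1.33) and GLK44 (170 pairs, ratio 1.23), while Orphan42 (418 pairs, 0.98) and Zm00001d033859, with the highest ratio (20 pairs, 1.43; adjusted permutation p = 0.116), did not pass.

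MYB34, MYBR3 and NAC109, of the same batch, had higher log2 odds ratios than any other pair known to share a batch, the next being bHLH47 and MYB81 at 2.83. For the 63 pairs with an unmatched regulator the batch is unknown. Zm00001d033859 and MYB21, at 4.13, are among them, so other same-batch pairs above 2.83 are not ruled out. With the number of regulators per gene kept, the shared targets of MYB34, MYBR3 and NAC109 exceeded expectation by at least 0.80 on the log2 scale. Often-listed genes alone therefore do not give the pattern. The list under NAC109 did not lie above that expectation with NAC5, NAC61 or NAC66. It is also the 1 list without its regulator's own gene, so that check of its label is missing. Simulated shared empty vectors reached a log2 odds ratio of 1.99, below the observed 4.48 to 5.24. That simulation leaves out real effects, so shared empty vectors and common targets cannot be told apart here, and either may account for the pattern. A common response behind these lists stays open, as untested.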
